A study of Mus musculus with 104 samples.

How the data were processed

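Total RNA from the striatum and cortex of BAC-CAG and BACHD mice and their WT littermates was sequenced as stranded TruSeq libraries, per the labels' protocols. The authors deposited 4 tables of whole-number counts per gene, 3 for BAC-CAG mice at 2, 6 and 12 months and 1 for BACHD mice at 12 months. Reads were aligned with STAR and counted with HTSeq on the GRCm38 (mm10) build, per the submitters' processing notes. Versions and settings of these tools were not given in the sources used here, and no human sequence is named among the references. The deposited counts were used as they were, without further scaling by the authors.

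Each column was linked to a sample through the animal tag in its title, and the group, sex and age of the sample were taken from the labels. All 104 libraries were used, 6 per group at 2 months, 8 at 6 and 12 months and 4 in the BACHD cohort, from separate animals within each group. The BAC-CAG tables hold 48795 Ensembl genes, of which 48349 were found in GENCODE M21, and the BACHD table holds 22981 symbols. Among the symbols of BAC-CAG genes 27 had been turned into dates and were left as they stand, and a symbol used by several Ensembl identifiers had the identifier added after its first use. Among those of BACHD genes 2 occurred more than once. For comparisons of the 2 lines 21528 symbols were shared as written and 823 were linked through older names, 22351 genes in total. Mitochondrially encoded genes were found in the BAC-CAG tables only.

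Depth was 36.5 M counts per library on average (SD 4.70, n = 104), between 25.8 and 48.4 M. Sex labels were checked with Xist and 4 Y-linked genes. Xist was between 544 and 1797 CPM in the 52 female libraries and at most 4.01 CPM in the 52 male libraries. The Y-linked genes summed to at least 148 CPM in males and to a median of 0.161 CPM in females, with 1 female library (striatum of a WT mouse at 2 months, replicate 2) at 43.0 CPM. That is 25.2% of the male median of its group, so RNA of a male animal in it is not excluded, and the library was kept in its group. No 2 libraries of a group agreed within sampling noise.

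Genes were tested with edgeR 4.0.16 in R 4.3.3, separately for each line, tissue and age, with TMM factors, the filterByExpr filter by genotype and sex as an additive covariate. The quasi-likelihood F test was two-sided, with adjustment by Benjamini and Hochberg and a threshold of 0.05. It gives no standard error, so that of a log2 change was derived as the size of the change divided by the square root of F. Whether the genotype effect differed between ages, tissues, lines or sexes was tested in 12 joint fits, as a contrast of the 2 genotype effects. Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, and with fry beside it. The 31 lists tested were written before the data were examined, as were the comparisons, the tests and most other settings. A list needed 5 tested members, which left 30 lists for BAC-CAG and 29 for BACHD mice, and lists were adjusted together in each comparison. A list of sex-linked genes served the label check only. Scores were the mean of log2(CPM + 1) over the genes of a list and were compared by exact two-sided permutation of the libraries.

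Striatum and cortex libraries came from the same animals, per the tags in the titles, except that 1 WT library of each tissue at 2 months had no partner. The deviations of the 2 tissues of an animal from their group means correlated with a median of 0.158 at 2 months (11 animals), 0.330 at 6 months (16), 0.169 at 12 months (16) and 0.190 in the BACHD cohort (8). The animal entered as a block only in an alternative fit of the tissue contrasts, as chosen before the data were examined.

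Genes were named by a rule set before the data were examined. It takes, per comparison, the 6 largest rises, the 6 largest falls and the 4 smallest p among called genes with a mean of at least 1 CPM, without predicted genes. It also takes up to 4 members with the smallest p per described list, up to 6 genes per interaction, and Htt. Genes outside it are marked as chosen after their values were seen.

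The other settings, chosen before the data were examined, were DESeq2 1.42.0, RLE factors, no low-count filter, limma-voom with quality weights, no sex covariate, a threshold of 0.1, the first surrogate variable from sva 3.50.0, leaving out each library in turn, 50 draws of 4 against 4 libraries at 12 months, a pseudocount of 0.1 or a median for scores, and an estimated correlation for lists. Chosen after the data had been seen were edgeR's legacy method, fits without libraries that stand apart, a cortical neuron score as covariate and further fits without single libraries. The choice of edgeR's default over its legacy method was itself made after counts of calls had been seen. Splits of the libraries into 2 mixed groups, at most 100 per comparison, gave the counts that chance gives. The fits were tested on simulated data, drawn from negative binomial distributions with the means, library sizes and dispersions of each comparison. In them 200 genes with a mean of at least 1 CPM were changed by known folds, so recovery of weaker genes was not tested. There edgeR recovered 92 to 100% of genes changed 2-fold and 81 to 92% of genes changed 1.5-fold, with false calls between 2.60 and 8.47%. In a simulated interaction (2 against 12 months, striatum) edgeR recovered 89% of genes changed 2-fold. With DESeq2 the false calls were 10.05 to 16.3%. Camera found a lowered list in all 8 simulated comparisons, with 2 to 4 other lists called beside it. Other lists share genes with the lowered list, so those called were not necessarily unchanged. Genes were drawn independently of each other, so the simulation does not test camera under correlation between genes. Nor does it hold a structure shared between samples, so its recovery and false calls may look better than in the real libraries. Cerebellum, named in the labels' protocols, was not analysed here.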

Results

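RNA was sequenced from the striatum and cortex of 2 mouse lines that model Huntington's disease, BAC-CAG and BACHD, and of their wild-type (WT) littermates. Both lines carry the human HTT gene, expanded in its polyglutamine repeat, on a bacterial artificial chromosome. BAC-CAG mice and WT mice were compared at 2 months (6 against 6 in each tissue), at 6 months (8 against 8) and at 12 months (8 against 8). BACHD mice and their own WT littermates were compared at 12 months (4 against 4 in each tissue). The 104 libraries came from 52 female and 52 male samples, and each group held as many females as males. Total counts were 36.5 M per library on average (SD 4.70, n = 104), between 25.8 and 48.4 M. Group means lay between 31.7 M (SD 3.78, n = 8, cortex of WT mice at 6 months) and 41.4 M (SD 5.85, n = 4, cortex of WT mice of the BACHD cohort). All 16 groups and both tissues were used. The labels also name cerebellum, which was not analysed here. Genes are named by their symbols in the tables, coordinates are those of the GRCm38 build, and fold changes are transgenic over WT on the log2 scale with their standard error (SE).

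Msantd1, a gene that lies next to Htt, was higher in all 52 transgenic libraries than in every WT library of the same cohort and tissue. In BAC-CAG striatum its log2 change was 2.32 (SE 0.15, n = 6) at 2 months, 2.16 (SE 0.07, n = 8) at 6 months and 2.44 (SE 0.22, n = 8) at 12 months. The adjusted p values from edgeR were 1.3e-05, 5.4e-13 and 3.3e-05. In BAC-CAG cortex it was 2.14 (SE 0.21) at 2 months, 1.76 (SE 0.12) at 6 months and 1.95 (SE 0.21) at 12 months. BACHD mice had larger values, 3.45 (SE 0.22, n = 4) in striatum and 3.33 (SE 0.24, n = 4) in cortex. At 12 months the striatal level was 16.1 ± 7.56 CPM (counts scaled to library size; SD, n = 8) in BAC-CAG against 2.89 ± 0.397 in WT mice, and 37.2 ± 10.7 in BACHD against 3.42 ± 0.757 in WT mice (n = 4 each). Msantd1 spans 34908012 to 34923839 on chromosome 5 and overlaps the 3′ end of Htt (34761740 to 34912534) on the same strand by 4523 bp, so which of the 2 genes, or which species' copy, its reads came from is uncertain.

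Htt itself, the mouse gene whose human counterpart is on the transgene, did not pass the edgeR threshold over all genes in any of the 8 comparisons. No human sequence is named among the references, so reads counted at Htt may come from the mouse gene or from the human transgene. The largest values were 0.37 (SE 0.07, adjusted p = 0.29) in BACHD striatum and 0.33 (SE 0.07, adjusted p = 0.53) in BACHD cortex. In BACHD striatum the level was 349 ± 31.7 CPM against 269 ± 12.3 (SD, n = 4 each), with all 4 BACHD libraries above the 4 WT libraries. That separation gives an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 allows, and 0.057 after adjustment over the 8 comparisons. BAC-CAG striatum at 12 months had 242 ± 11.2 CPM against 219 ± 7.24 (SD, n = 8 each), a log2 change of 0.15 (SE 0.03). The edgeR adjusted p was 0.078, the exact permutation p was 0.00062 and its value adjusted over the 8 comparisons was 0.0050, with 8 of 8 libraries above the WT median. DESeq2 put Htt past its threshold in that comparison and in both BACHD comparisons, with adjusted p of 0.0047, 0.00085 and 0.0023. At 2 and 6 months the striatal log2 changes were 0.10 (SE 0.05) and 0.04 (SE 0.06), and in BAC-CAG cortex they were 0.09, 0.00 and 0.08 from 2 to 12 months.

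**Figure D1:**
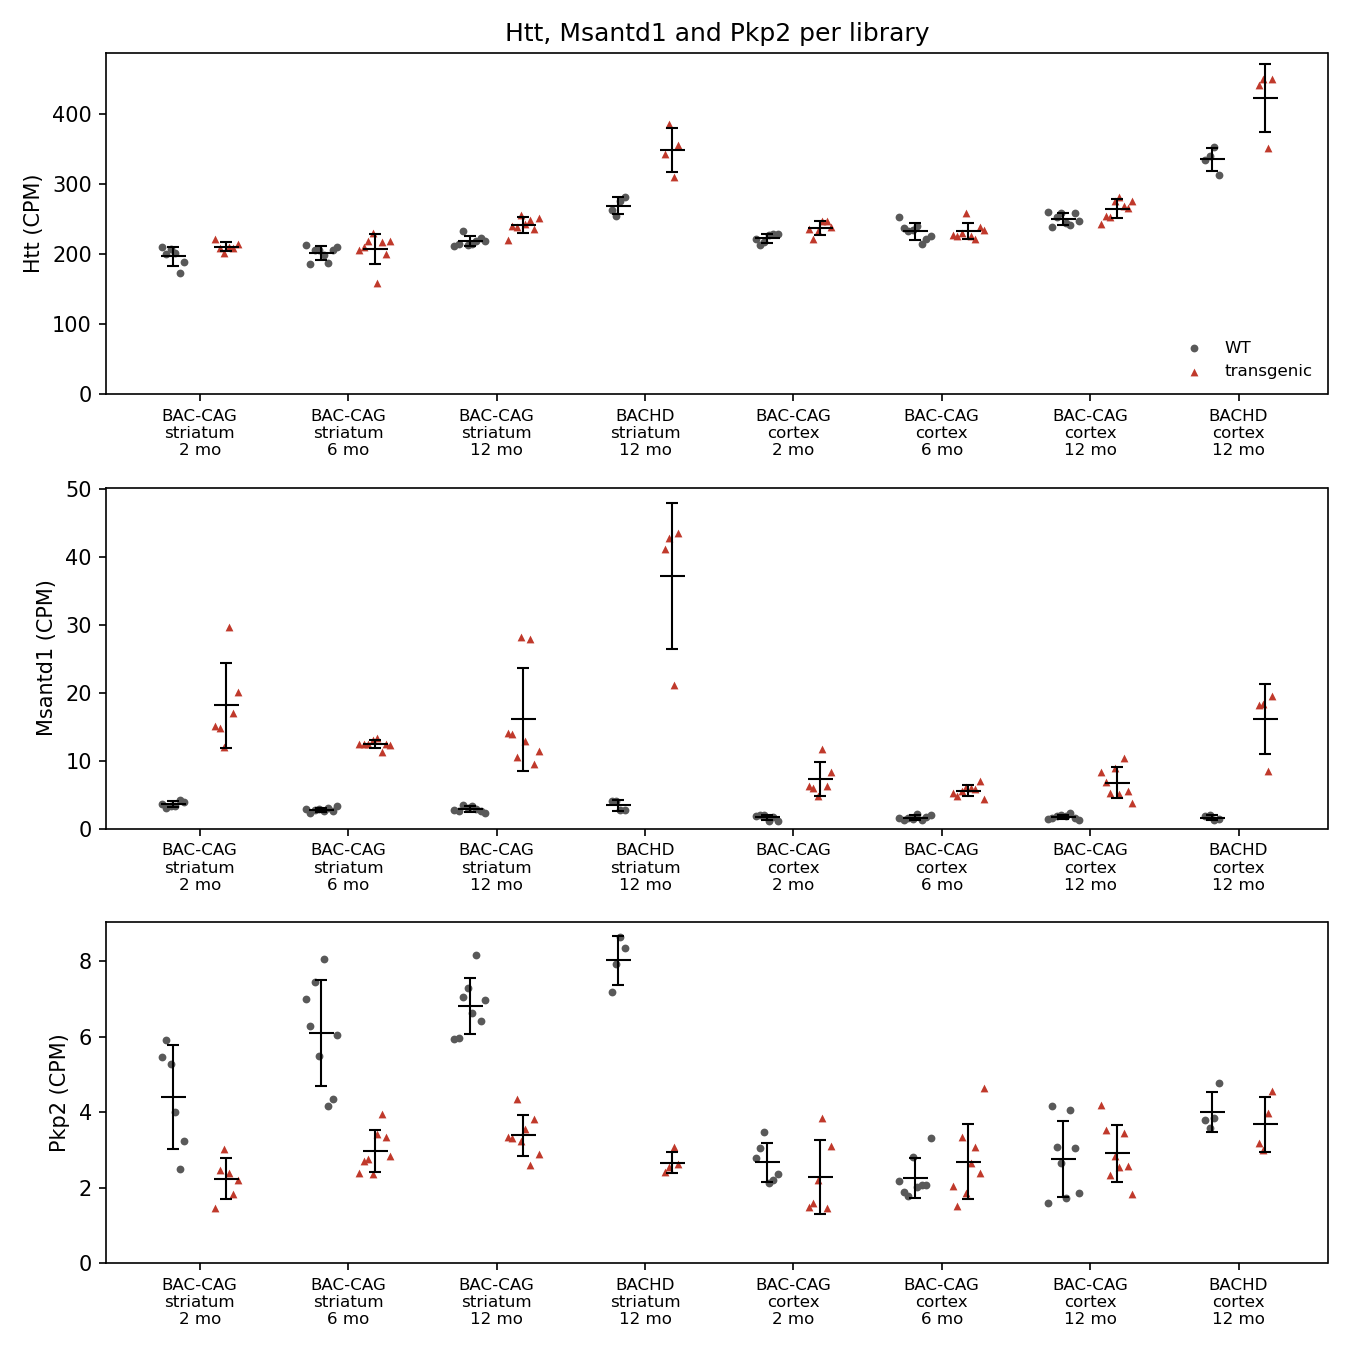
CPM of Htt, Msantd1 and Pkp2 in each library (grey circles, WT; red triangles, transgenic), with the mean and SD of each group as black bars, for the 8 comparisons on the x axis. Msantd1 was higher in all 52 transgenic libraries, and Pkp2 was lower without overlap in BAC-CAG striatum at 6 and 12 months and in BACHD striatum.

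The question in BAC-CAG striatum was which genes differ from WT littermates, and at which age. At 12 months 64 of 18246 tested genes passed the edgeR test, 18 higher and 46 lower, with 2276 genes at an unadjusted p under 0.05 where chance gives 912. Pkp2 (chromosome 16, 16213318 to 16272712), the gene of a desmosome plaque protein, fell by 1.01 (SE 0.10, adjusted p = 8.4e-05), from 6.80 ± 0.741 CPM in WT to 3.39 ± 0.540 in BAC-CAG mice (SD, n = 8 each). Other falls with the smallest p were in the kinase gene Cdk19 (-0.34, SE 0.04) and in Pcp4, a regulator of calmodulin (-0.42, SE 0.06). Among the largest falls were Odf4 (-1.28, SE 0.20), Serpinb1b (-1.17, SE 0.24), Sec14l3 (-1.16, SE 0.17), Phex (-1.13, SE 0.19) and Ddit4l (-1.03, SE 0.17), all with 8 of 8 BAC-CAG libraries below the WT median. Odf4 was near 1 CPM in BAC-CAG mice (0.995 ± 0.444, n = 8). Among the largest rises, after Msantd1, were Tmc3 (1.43, SE 0.25), the titin gene Ttn (0.76, SE 0.15), Zfp488 (0.74, SE 0.14), the filamin gene Flnc (0.69, SE 0.14) and the potassium channel gene Kcng1 (0.65, SE 0.11). Of the 64 genes, 37 moved by less than 1.5 times. In 23 of them no BAC-CAG library overlapped a WT library, which 0.159% of all tested genes showed. The count was 282 with DESeq2 (61 shared) and 199 with limma's quality weights (64 shared).

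Genes that mark striatal projection neurons, the main neurons of the striatum, were lower as a group at 12 months. Of 39 tested members, 36 had a negative log2 change and the median was -0.27. Over all genes 4 fell: Actn2 (-0.62, SE 0.09, adjusted p = 0.0041), which encodes an actin cross-linker of the spine, the enkephalin precursor gene Penk (-0.72, SE 0.11, adjusted p = 0.0075), the regulator of G-protein signalling Rgs4 (-0.34, SE 0.06, adjusted p = 0.015) and the cannabinoid receptor gene Cnr1 (-0.48, SE 0.09, adjusted p = 0.035). Adjusted over the list alone, 28 members fell. Penk counts were 786 ± 145 CPM against 1298 ± 165 (SD, n = 8 each), with no overlap between the groups. The camera test gave the list an adjusted p of 2.3e-22 with the preset correlation, and an adjusted p = 0.23 with an estimated correlation. Its mean score per library was 8.05 ± 0.202 against 8.34 ± 0.160 (SD, n = 8 each), a difference of -0.285 (exact two-sided permutation p = 0.0073, adjusted over the lists p = 0.045), and 8 of 8 BAC-CAG libraries lay below the WT mean. As a median over the genes the difference was -0.162 (exact permutation p = 0.053). Markers of the indirect pathway, the projection neurons that express Drd2, had a median of -0.37 over 7 members. Penk, which is also in the identity list, fell over all genes, so the calls of both lists are not independent. Adjusted over the list alone 5 members fell, among them Gpr6 (-0.38, SE 0.11), Adora2a (-0.48, SE 0.15) and Drd2 (-0.32, SE 0.10). Their score difference was -0.33 (exact permutation p = 0.0034, adjusted p = 0.026, lower in 7 of 8 libraries), and camera gave adjusted p of 3.8e-06 and, with an estimated correlation, p = 0.23. The 8 direct-pathway markers had a median of 0.00 and no camera call (adjusted p = 0.81). None of the 8 passed over all genes. Adjusted over the list alone, Eya1 rose (0.31, SE 0.09) while Chrm4 (-0.30, SE 0.09) and Drd1 (-0.27, SE 0.10) fell.

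Genes of cAMP and G-protein signalling followed, with a median of -0.19 over 29 members. Rgs4 fell over all genes and 13 members fell adjusted over the list alone, among them Pde10a (-0.44, SE 0.11), the striatal phosphodiesterase, Rgs7bp (-0.20, SE 0.05) and Ppp1r1a (-0.23, SE 0.06). The ion channel list (32 genes, median -0.10) had no member past the test over all genes and 5 lower members adjusted over the list alone, such as the calcium release channel genes Itpr1 (-0.28, SE 0.07) and Ryr1 (-0.65, SE 0.16) and the sodium channel subunit gene Scn4b (-0.50, SE 0.13). Camera called both lists (adjusted p of 6.3e-09 and 8.9e-05), with adjusted p = 0.23 and 0.27 with an estimated correlation. Rgs4 and Ryr1 are also in the identity list, so these calls are not independent of the call of that list. The clustered protocadherins, adhesion genes encoded in 3 clusters, went the other way, with a median of 0.14 over 56 members. Pcdhb3 rose over all genes (0.37, SE 0.07, adjusted p = 0.020), and adjusted over the list alone 15 members rose and 2 fell (camera adjusted p = 2.1e-05, p = 0.29 with an estimated correlation). Circadian clock genes had a median of -0.09 over 17 members, with 0 past the test over all genes and 3 lower adjusted over the list alone, Dbp (-0.34, SE 0.07), Ciart (-0.36, SE 0.09) and Bhlhe41 (-0.16, SE 0.05). Camera gave them an adjusted p of 0.00020, and p = 0.23 with an estimated correlation.

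Markers of other cell types were also lower in these BAC-CAG libraries. The microglial list had a median of -0.15 over 22 genes, with 0 past the test over all genes and 11 lower adjusted over the list alone, among them P2ry12 (-0.23, SE 0.05) and Cx3cr1 (-0.19, SE 0.05). Its score was lower in 8 of 8 libraries (difference -0.140, exact permutation p = 0.0011), and camera gave adjusted p of 1.0e-10 and, with an estimated correlation, p = 0.13. Astrocyte genes (20, median -0.11, among them Aqp4 at -0.24, SE 0.07) and endothelial genes (20, median -0.11) each had 2 lower members adjusted over the list alone, and the oligodendrocyte list (22, median -0.18) had 4, among them Mal (-0.44, SE 0.11). Camera called these 3 lists as well (adjusted p of 1.6e-07, 4.4e-06 and 1.2e-05), with adjusted p = 0.19, 0.23 and 0.49 with an estimated correlation. Cortical excitatory neuron genes had a median of 1.13 over 18 members, 17 of them positive and 0 past either adjustment, such as Neurod2 (1.80, SE 0.79). Their scores stood at 5.29 and 5.72 in BAC-CAG replicates 2 and 7, above the other 14 libraries (2.93 to 4.39). Without these 2 libraries 16 genes passed, 15 of them among the 64, and the identity score differed by -0.226 (exact permutation p = 0.023). With the cortical score as a covariate 13 passed, all among the 64. Ddit4l, Serpinb1b, Flnc, Kcng1, Tmc3, Ttn and Zfp488 lost their call in both fits (adjusted p 0.0580 to 0.155) with log2 changes of similar size, such as 1.42 and 1.34 for Tmc3 and -0.98 and -0.96 for Ddit4l, and Phex in that with the covariate (0.0507). Camera called 16 of 30 lists at 12 months, 0 of them with an estimated correlation, and fry called 3.

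The count of 64 depended on single libraries. It was 22 without BAC-CAG replicate 6, 23 without replicate 4, 30 without 3, 34 without 7, 39 without 1, 102 without 5 and 260 without 8. It was 26 without WT replicate 1, 34 without 3, 39 without 4, 23 without 5, 34 without 6 and 29 without 7. Msantd1, Pkp2, Cdk19, Pcp4, Actn2, Penk, Rgs4, Odf4, Sec14l3, Phex and Ddit4l passed in each of the 16 fits that left out 1 library. Zfp488 passed in 6 of the 16, Ttn, Flnc and Cnr1 in 5 and Serpinb1b in 4, with adjusted p up to 0.0877, 0.0890, 0.109, 0.1001 and 0.118. Tmc3 and Kcng1 missed the threshold without WT replicate 1, Tmc3 also without BAC-CAG replicate 4 (adjusted p = 0.0525) and Kcng1 without replicate 6 (0.0516), and Pcdhb3 without BAC-CAG replicate 4 or 6 or WT replicate 5.

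**Figure D2:**
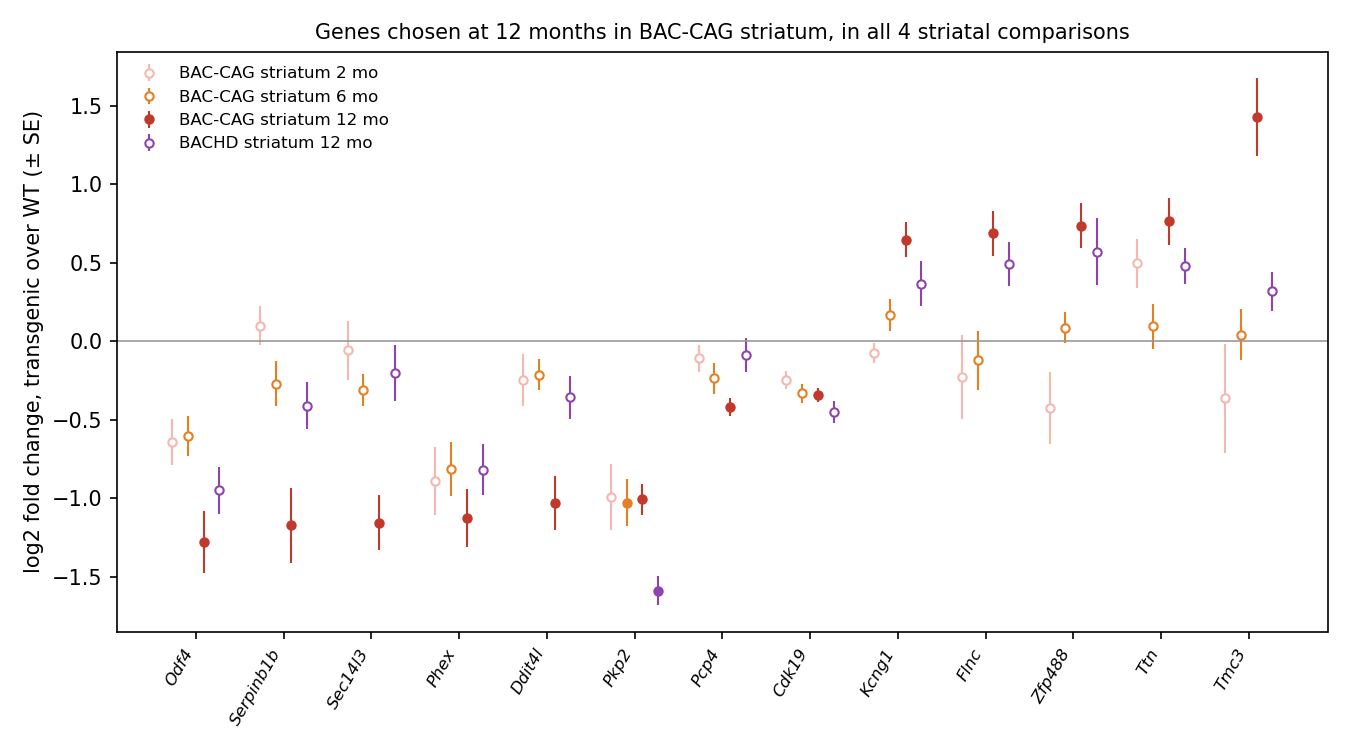
Log2 fold change, transgenic over WT, with its SE, of the 13 genes other than Msantd1 picked by the naming rule in BAC-CAG striatum at 12 months, for the 4 striatal comparisons (filled points, adjusted p under 0.05; open points, not past it). Pkp2 passed in 3 of the 4 comparisons, between -0.99 and -1.59 in all of them.

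At the younger ages few striatal genes passed. At 2 months Msantd1 alone of 17923 genes passed in edgeR (1106 at an unadjusted p under 0.05), and at 6 months Msantd1 and Pkp2 of 17773 (805 unadjusted). Pkp2 fell by 1.03 at 6 months (SE 0.15, adjusted p = 0.016, 2.97 ± 0.555 against 6.10 ± 1.40 CPM, SD, n = 8 each, no overlap). At 2 months its log2 change was -0.99 (SE 0.21, adjusted p = 0.75, n = 6 each), lower in 6 of 6 libraries, with an exact two-sided permutation p of 0.0043 for this gene alone (0.012 adjusted over the 8 comparisons). That adjustment includes the comparisons in which Pkp2 was called, so the adjusted value is not independent of them. Actn2 was at -0.50 (SE 0.08, adjusted p = 0.43) at 2 months and -0.48 (SE 0.08, adjusted p = 0.054) at 6 months, and Cdk19 at -0.25 (SE 0.05) and -0.33 (SE 0.06). The identity list had medians of -0.08 at 2 months (34 of 39 negative) and -0.11 at 6 months (33 of 39 negative). Adjusted over the list alone, Actn2 fell at 2 months, and Actn2, Rgs4 (-0.26, SE 0.07) and Cnr1 (-0.39, SE 0.12) fell at 6 months, with 0 over all genes at either age. Camera called the list at both ages (adjusted p of 0.00025 and 5.1e-11), with adjusted p = 0.67 and 0.43 with an estimated correlation. The score differed by -0.0741 at 2 months (exact permutation p = 0.29, lower in 5 of 6 libraries) and by -0.107 at 6 months (p = 0.058, lower in 7 of 8). At 6 months interneuron genes had a median of 0.06 and 4 higher members adjusted over the list alone, the corticotropin-releasing hormone gene Crh (0.88, SE 0.23), Vip (0.70, SE 0.19), Calb2 (0.64, SE 0.23) and Nkx2-1 (0.21, SE 0.07), with 0 over all genes (camera adjusted p = 0.00085, p = 0.18 with an estimated correlation). Camera called 15 and 13 of 30 lists at 2 and 6 months, 0 of them with an estimated correlation, and 4 at 2 months without WT replicate 6. DESeq2 called 6 genes at 2 months and 24 at 6 months. The Pkp2 call at 6 months was lost without BAC-CAG replicate 1, 2, 3 or 8 or WT replicate 1 or 3 (adjusted p 0.0547 to 0.0627), and 4 genes passed without BAC-CAG replicate 4 or 5.

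**Figure D3:**
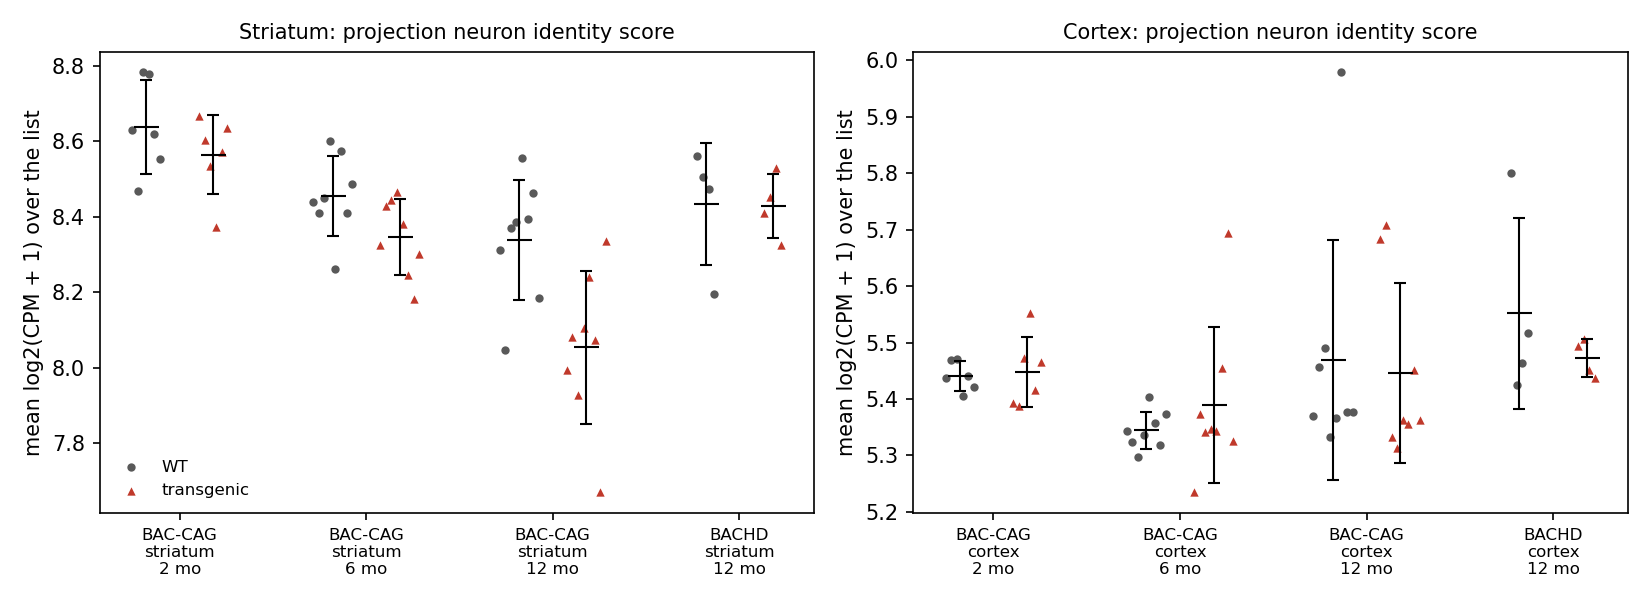
Mean log2(CPM + 1) over the 39 projection neuron identity genes (38 in BACHD cortex) in each library, striatum on the left and cortex on the right, with the mean and SD of each group as black bars; the 2 y axes differ and start above 0. The striatal difference was -0.285 in BAC-CAG mice at 12 months and -0.00500 in BACHD mice (-0.0843 without WT replicate 4).

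In BAC-CAG cortex Msantd1 was the one gene past the edgeR test at 2 months (of 17760, 1238 at an unadjusted p under 0.05) and at 12 months (of 17950, 457 unadjusted). At 6 months 2 of 17563 genes passed (635 unadjusted). The other was Chrnb3 (chromosome 8, 27368711 to 27399730), a nicotinic acetylcholine receptor gene, which fell by 1.04 (SE 0.15, adjusted p = 0.010), from 3.09 ± 0.410 to 1.52 ± 0.428 CPM (SD, n = 8 each, no overlap). Chrnb3 had log2 changes of -0.51 (SE 0.17, adjusted p = 0.62) at 2 months, -1.003 (SE 0.21, adjusted p = 0.41) at 12 months and -1.09 (SE 0.16, adjusted p = 0.28) in BACHD cortex. At 2 months myelin genes had a median of -0.26, with all 22 negative and 2 lower adjusted over the list alone, Mobp (-0.39, SE 0.10) and Olig1 (-0.22, SE 0.06). Other non-neuronal lists were also negative there, with medians of -0.17 for oligodendrocyte precursors, -0.13 for microglia and -0.87 for choroid plexus (camera adjusted p of 0.0055, 5.8e-07 and 0.0029, p = 0.42, 0.38 and 0.41 with an estimated correlation). The choroid plexus gene Ttr was uneven among WT libraries, at 32.0 ± 63.4 CPM (SD, n = 6) with a maximum of 161. Its median was 4.43 CPM in WT and 5.55 CPM in BAC-CAG mice. At the same age circadian genes had a median of 0.18, with Hlf (0.16, SE 0.04) higher adjusted over the list alone, and 4 protocadherins were higher, among them Pcdhb2 (0.46, SE 0.10) and Pcdhb3 (0.37, SE 0.10). No member of any of these lists passed over all genes. Camera called the myelin, circadian and protocadherin lists (adjusted p of 2.7e-10, 7.3e-07 and 0.0020), with adjusted p = 0.39, 0.25 and 0.18 with an estimated correlation. At 12 months interferon-response genes had a median of 0.15, with 24 of 25 positive, 0 past the test over all genes and Irf7 (0.67, SE 0.13, 8 of 8 libraries above the WT median) higher adjusted over the list alone. Camera gave an adjusted p of 2.1e-09, and p = 0.16 with an estimated correlation. The striatal identity list was not called in cortex at any age, and its scores differed by 0.00713, 0.0452 and -0.0226 at 2, 6 and 12 months. Camera called 10, 6 and 8 of 30 lists in cortex at the 3 ages, 0 of them with an estimated correlation, and without single libraries 2 to 11 at 6 months and 4 to 12 at 12 months. DESeq2 called 24, 2 and 10 genes. A second gene passed at 2 months without WT replicate 4, and at 12 months without BAC-CAG replicate 5, WT replicate 5 or WT replicate 6.

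BACHD striatum at 12 months, compared with its WT littermates, had 6 of 15861 genes past the edgeR test, 4 higher and 2 lower, with 833 at an unadjusted p under 0.05 (chance gives 793). Pkp2 fell by 1.59 (SE 0.09, adjusted p = 0.00031), from 8.02 ± 0.644 to 2.66 ± 0.285 CPM, and the neurotensin gene Nts fell by 1.44 (SE 0.14, adjusted p = 0.0057), from 11.9 ± 1.59 to 4.40 ± 0.679 CPM (SD, n = 4 each). Msantd1 rose, as did the semaphorin receptor gene Plxnb3 (0.52, SE 0.06, adjusted p = 0.016). The 2 others were Lars2 (chromosome 9, 123366927 to 123462666), the mitochondrial leucyl-tRNA synthetase gene (2.85, SE 0.20, 992 ± 355 against 137 ± 27.7 CPM), and Rn45s, the precursor of ribosomal RNA (1.32, SE 0.11, 8296 ± 945 against 3313 ± 370 CPM). The libraries thus differed in reads counted at Rn45s, and other ribosomal RNA was not measured. All 6 genes separated the groups, which 3.22% of all tested genes did. Actn2 (-0.72, SE 0.14, adjusted p = 0.29) and Cdk19 (-0.45, SE 0.07, adjusted p = 0.14) were lower in 4 of 4 libraries without passing over all genes. In the identity list 1 member rose and 1 fell adjusted over the list alone, the dynorphin precursor gene Pdyn (0.47, SE 0.09) and Actn2, with a median of 0.00, 0 over all genes and no camera call (adjusted p = 0.90). Its score differed by -0.00500 (exact permutation p = 1.0), by -0.0843 without WT replicate 4 (p = 0.20) and by 0.1355 as a median over the genes. Myelin genes had a median of 0.13 over 22 members (camera adjusted p = 5.2e-05, p = 0.76 with an estimated correlation), and cortical excitatory genes a median of -0.78 (0.0072, p = 0.95 with an estimated correlation), with 0 members of either past the test over all genes or adjusted over the list alone. The cortical score was 5.13 in WT replicate 4 and 3.18 to 3.68 in the other 7 libraries, and without WT replicate 4 the count was 25. Nts missed the threshold without BACHD replicate 4 (adjusted p = 0.0506, 4 genes left), Plxnb3 without WT replicate 2 or any single BACHD replicate, and DESeq2 called 35 genes. Camera called 6 of 29 lists, 0 with an estimated correlation and 5 to 11 without single libraries.

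In BACHD cortex Msantd1 alone of 15839 genes passed the edgeR test (1008 at an unadjusted p under 0.05, 792 by chance). Pkp2 was at -0.13 (SE 0.11), Lars2 at -0.04 (SE 1.42) and Rn45s at 0.15. Choroid plexus genes had a median of -0.78, with 0 past the test over all genes and 5 lower adjusted over the list alone, the transthyretin gene Ttr (-3.34, SE 0.80), Clic6 (-1.88, named after its values were seen), the prolactin receptor gene Prlr (-1.60, SE 0.39), the klotho gene Kl (-0.97, SE 0.28) and Kcnj13 (-0.49, SE 0.15). Ttr varied 6.81 ± 2.96 against 75.6 ± 86.5 CPM (SD, n = 4 each). Camera called the list (adjusted p = 0.00028), with an adjusted p = 0.83 with an estimated correlation. The identity list had a median of -0.06, and the calcium sensor gene Hpca (-0.22, SE 0.04) and Ryr1 (-0.33, SE 0.07) fell adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.015, p = 0.83 with an estimated correlation). DESeq2 called 18 genes, none of them Msantd1, for which it gave no adjusted p. Camera called 8 of 29 lists, 0 with an estimated correlation and 2 to 15 without single libraries. The edgeR count was 2 without WT replicate 2 and 4 without BACHD replicate 3.

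Whether the genotype effect changed with age, tissue, line or sex was tested as an interaction, given as older minus younger, striatum minus cortex, BAC-CAG minus BACHD and male minus female. In striatum no gene passed between 2 and 6 months (666 of 18633 at an unadjusted p under 0.05), between 6 and 12 months (741 of 18770) or between 2 and 12 months (1458 of 18995, 950 by chance) with edgeR, and DESeq2 called 0, 0 and 12. The smallest p values between 2 and 12 months included the cytokine gene Il33 (-0.93, SE 0.19) and Kcng1 (0.71, SE 0.15), both with an adjusted p of 0.15. The identity list had a median difference of -0.20 between 2 and 12 months (camera adjusted p = 3.1e-10, p = 0.42 with an estimated correlation). Cortical excitatory scores were highest in transgenic replicates 2 and 7 at 12 months (5.29 and 5.72) but in WT replicate 2 at 2 months (4.72). These libraries lie on opposite sides of the contrast, so cortical tissue cannot be told apart from age here. The list was not tested without them. In cortex between 2 and 12 months no gene passed (832 of 18726, DESeq2 0), while interferon genes differed by a median of 0.22 (5.9e-07, p = 0.17 with an estimated correlation) and microglial genes by 0.21 (7.2e-10, p = 0.32 with an estimated correlation).

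Between striatum and cortex, BACHD mice differed in Pkp2 (-1.46, SE 0.13, adjusted p = 0.00028) and in the ubiquitin ligase gene Rnf144b (-0.45, SE 0.06, adjusted p = 0.024). With the animal as a block Pkp2 alone passed. In BAC-CAG mice Pkp2 differed by -1.30 (SE 0.25) at 6 months and -1.09 (SE 0.23) at 12 months, with edgeR adjusted p of 0.26 and 0.20. DESeq2 called it at both ages. The one edgeR call at 12 months was 2610316D01Rik (0.50, SE 0.09, adjusted p = 0.047), a processed transcript on chromosome 3 (45280437 to 45378260), which rose in striatum (0.41, SE 0.07, adjusted p = 0.014). That call was lost with the animal as a block and with no low-count filter. At 2 months 0 genes differed (756 unadjusted, DESeq2 0, and with the animal as a block Megf11 at 0.63, adjusted p = 0.022, named after its values were seen) and at 6 months 0 (495, DESeq2 1). The identity list differed by a median of -0.22 at 12 months (camera adjusted p = 1.9e-14, p = 0.26 with an estimated correlation). BAC-CAG striatal replicates 2 and 7, with high cortical excitatory scores, were kept in this contrast, and the list was not tested without them.

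Between BAC-CAG and BACHD mice at 12 months, Lars2 was the one striatal gene whose effect differed (-2.78, SE 0.23, adjusted p = 5.2e-07), and in cortex 0 did (506 of 15878 unadjusted, DESeq2 0). Of the 64 genes called in BAC-CAG striatum, 58 were tested in BACHD striatum, and 50 had the same sign there (86.2%, 95% exact binomial interval 74.6 to 93.9, as if genes were independent). Msantd1 and Pkp2 passed in both, where chance gives 0.020 genes. Across all genes, which are not independent, the 2 sets of log2 changes correlated at r = -0.19 and rho = -0.013, with 50.04% of the same sign. The identity list differed between the lines by a median of -0.26 (camera adjusted p = 7.8e-13, p = 0.39 with an estimated correlation). Cortical excitatory scores were high in transgenic replicates 2 and 7 of the BAC-CAG cohort (5.29 and 5.72) but in WT replicate 4 of the BACHD cohort (5.13). These libraries lie on opposite sides of the contrast, so cortical tissue cannot be told apart from line here. The list was not tested without them. In cortex the interferon list differed by a median of 0.27, at 0.15 in BAC-CAG and -0.09 in BACHD mice. This difference passed camera with the preset correlation (adjusted p = 6.1e-11) and with an estimated one (adjusted p = 0.043), but not fry (adjusted p = 0.12). Of 63 genes called at 12 months and tested at 6 months in BAC-CAG striatum, 61 had the same sign (96.8%, against 58.4% of all genes). In cortex at 12 months 43 of 60 did (71.7%, against 52.9% of all genes), but both tissues came from the same animals, which can raise this share without any effect of genotype. Between the sexes no striatal gene differed in its genotype effect at 6 months (2242 of 18408 unadjusted, DESeq2 11) or 12 months (1065 of 19045, DESeq2 6). The smallest p values at 12 months were those of the activity-regulated genes Btg2 (1.86, SE 0.28, adjusted p = 0.076) and Fos (2.67, SE 0.42, adjusted p = 0.076).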

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

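The tests of an age-dependent response, of transgene reads, of the 2 Lars2 explanations and of Msantd1 in both tissues of an animal were chosen after seeing the result. The test of transgene dose was written before the data were examined.

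Of 96 checks by Dixon's test, each of a single measure in a group, 10 found a library far from the others. Chance singles out a library in about 1 in 20 checks, which is 4.8 here. In BACHD mice Msantd1 was low in male replicate 3 in both tissues, at 21.2 CPM in striatum (41.2 to 43.7 in the other 3) and 8.53 CPM in cortex (18.3 to 19.5). Htt was low in the same cortex library, at 351 CPM (443 to 451 in the others). In BAC-CAG mice at 6 months Htt stood at 159 CPM in striatum replicate 5 (201 to 230 in the others) and at 258.5 CPM in cortex replicate 4 (222 to 239). The striatal identity score was 5.98 in cortex of WT replicate 6 at 12 months (5.33 to 5.49 in the others). The cortical excitatory score was 6.985 in cortex of WT replicate 4 at 2 months (6.92 to 6.94). Total counts were low at 12 months in cortex of WT replicate 2 (26.5 M, others 34.2 to 40.6), striatum of WT replicate 2 (27.35 M, others 34.6 to 40.9) and striatum of BAC-CAG replicate 1 (29.3 M, others 35.1 to 39.8).

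The genotype effect differed between groups, by a tested interaction, for 4 genes at 12 months. Between striatum and cortex these were Pkp2 (-1.46) and Rnf144b (-0.45) in BACHD mice and 2610316D01Rik (0.50) in BAC-CAG mice. With the animal as a block Rnf144b and 2610316D01Rik did not pass, and 2610316D01Rik was also lost without the low-count filter. Between BAC-CAG and BACHD striatum it was Lars2 (-2.78).

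Msantd1 was higher in every transgenic library, and its level differed between transgenic animals. The tables argue against a response that appears only with age, since the log2 change was already 2.32 in striatum at 2 months. Within groups of BAC-CAG mice, its deviations in striatum and cortex of the same animal correlated (r = 0.821, n = 22 animals, permutation p = 1e-05, the smallest these permutations can give, adjusted over 3 relations p = 3e-05, rho = 0.770 with permutation p = 9e-05, r = 0.778 without the 2 farthest animals), in line with a property of the animal. Human transgene reads counted at the mouse gene could also give the rise, and 52 of 52 transgenic libraries stood above every WT library of their cohort and tissue, which either explanation allows. For transgene dose seen in Htt too, r was 0.136 between striatal Msantd1 and Htt (n = 22, permutation p = 0.51, adjusted p = 0.51, rho = 0.341 with permutation p = 0.12, r = -0.00953 without the 2 farthest animals). This r lay under the limit written beforehand, below which the explanation was to count as argued against. A margin for the spread of r was added after the values were seen, and with that margin the explanation stays open. The test covered BAC-CAG striatum only, where mean Htt was 1.03 to 1.11 times that of WT mice, which leaves dose little room to show. BACHD mice, at 1.30 times in striatum and 1.26 in cortex, were not part of it. There male replicate 3 had the lowest Msantd1 and the lowest Htt in both tissues, but that is a single animal.

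Lars2 and Rn45s were higher in BACHD striatal libraries. Ribosomal RNA carried over in some libraries might give this without any effect of genotype, and 1 WT library, cortex replicate 1, stood at or above the lowest BACHD striatal library (747 CPM) for Lars2, and for Rn45s as well. Cortex BACHD replicate 3 was also high for both, at 974 CPM for Lars2 and 8480 CPM for Rn45s. An effect of the BACHD genotype was not seen in cortex, where the log2 change of Lars2 was -0.0366 (SE 1.42), too wide to exclude it. Both explanations stay open.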

How the results depend on the processing

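No named gene call turned its direction in an alternative that gave it a value, with 226 of 246 values, without those that left out single libraries, still past the threshold and 20 weaker. Of the other alternative values 519 stayed alike. Where not said otherwise, the cause was not tested. At this depth and number of animals the median SE of a log2 change was 0.0656 to 0.0826, which limits what can be seen of smaller changes. Between TMM, RLE and DESeq2 factors the median over all genes moved by at most 0.0027, and no list median described in the report turned.

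With DESeq2 the gene counts were 6, 24 and 282 (95 higher, 187 lower) in BAC-CAG striatum at 2, 6 and 12 months, 24 (11 higher, 13 lower) and 10 (5 and 5) in cortex at 2 and 12 months, 35 (16 and 19) in BACHD striatum and 18 (7 and 11) in BACHD cortex. With voom and quality weights they were 6 and 199 in BAC-CAG striatum at 6 and 12 months and 12 in BACHD striatum. With the surrogate variable they were 10 in BAC-CAG striatum at 6 months, 3 in cortex at 12 months, 36 in BACHD striatum and 2 in BACHD cortex. Without a low-count filter there were 3 in BAC-CAG striatum at 6 months and 3 in cortex at 2 months, without sex 3 in striatum at 6 months, and at a threshold of 0.1 3 and 138 in striatum at 6 and 12 months. Without the libraries that stand apart there were 16 in BAC-CAG striatum at 12 months, 25 in BACHD striatum and 2 in BACHD cortex, and with the cortical score 3 and 13 in BAC-CAG striatum at 6 and 12 months and 30 in BACHD striatum. Draws of 4 against 4 libraries, which are fewer, gave a median of 0.5 genes in striatum (0 to 261, 8 of 50 draws with 6 or more) and 0 in cortex (0 to 9). Leaving out 1 library gave 1 to 4 genes in striatum at 6 months, 22 to 260 at 12 months, 1 to 2 in cortex at 2 and 12 months, 4 to 25 in BACHD striatum and 1 to 4 in BACHD cortex.

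The list count of each of the 8 genotype comparisons became 0 with an estimated correlation. Fry gave 0, 1 and 3 lists in BAC-CAG striatum, 0, 1 and 0 in cortex and 0 in BACHD mice. Without the libraries that stand apart there were 11 in cortex at 6 months and 4 in BACHD cortex. Leaving out 1 library gave 4 to 15 lists in striatum at 2 months, 11 to 17 at 6 and 14 to 19 at 12 months, 8 to 12, 2 to 11 and 4 to 12 in cortex, 5 to 11 in BACHD striatum and 2 to 15 in BACHD cortex.

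As a median over the genes, the identity score differed by -0.162 in BAC-CAG striatum at 12 months (exact permutation p = 0.053, weaker), and it turned to 0.0516 in cortex at 12 months and 0.1355 in BACHD striatum. Leaving out 1 library gave -0.135 to -0.0841 in striatum at 6 months, -0.0137 to 0.0190 in cortex at 2 months, -0.0601 to 0.0502 in cortex at 12 months, -0.08425 to 0.03715 in BACHD striatum and -0.121 to 0.00367 in BACHD cortex, where it was 0.0105 without the libraries that stand apart. For Htt in cortex at 6 months the range was -0.0219 to 0.0231, with -0.0187 without the libraries that stand apart. Htt passed with DESeq2 in BAC-CAG striatum at 12 months (0.1465), BACHD striatum (0.3765) and BACHD cortex (0.3365), and in 1 of the 8 fits of BACHD cortex without single libraries (range 0.274 to 0.417, passed without BACHD replicate 3).

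Among interactions, DESeq2 gave 12 genes between 2 and 12 months in striatum, 1 and 9 between tissues at 6 and 12 months, 19 between tissues in BACHD mice, and 11 and 6 between sexes at 6 and 12 months. Without a filter there were 0 between tissues at 12 months, 1 in BACHD mice and 2 between sexes at 12 months (2 also at a threshold of 0.1), and without sex 1 in BACHD mice. With the animal as a replicate block there were 1, 0 and 1 between tissues at 2 and 12 months and in BACHD mice, and the block changed no other call. Leaving out 1 library gave 1 to 20 between tissues in BACHD mice, and 1 to 2 in striatum and 0 to 1 in cortex between the lines. The same-sign share with DESeq2 was 88.65% between 6 and 12 months, 70.27% between the lines and 70.9% between the tissues. For genes called in the first set it was 100% in all 3 relations, with 2, 5 and 1 genes, too few to read.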

Other observations

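Other gene groups were lower or higher as lists without a member past the test over all genes. In BAC-CAG striatum at 2 months myelin genes had a median of -0.34 (21 of 22 negative, camera adjusted p = 1.1e-04, adjusted p = 0.67 with an estimated correlation). Among them, Mobp (-0.40, SE 0.21, n = 6 each) did not pass over the list alone. In the same libraries the medians were -0.26 for ependymal cells, 0.18 for interneurons and 1.80 for choroid plexus (camera adjusted p of 0.022, 1.1e-04 and 0.034, p = 0.67 for each with an estimated correlation), and -0.21 for reactive astrocytes, which camera did not call. The choroid plexus score was on the side of the rise in only 3 of 6 BAC-CAG libraries. Ttr was at 244 ± 542 CPM in them (SD, n = 6), with a maximum of 1349. Its median was 29.6 CPM there and 33.0 CPM in WT mice. Microglial genes had a median of -0.15 at that age, with Fcrls (-1.88, SE 0.59) and the complement gene C1qc (-0.53, SE 0.23) not past the list alone (camera adjusted p = 0.0011, p = 0.67 with an estimated correlation). Genes encoded by mitochondrial DNA had a median of -0.15 in striatum at 6 months, where the complex I genes mt-Nd5 (-0.35, SE 0.12) and mt-Nd6 (-0.31, SE 0.07) fell adjusted over the list alone and 0 fell over all genes (camera adjusted p = 1.1e-04, p = 0.43 with an estimated correlation). The same list had a median of -0.14 in cortex at 2 months, where mt-Nd5 (-0.25, SE 0.06), mt-Nd2 and mt-Nd6 fell adjusted over the list alone. In striatum at 12 months its median was -0.18 (camera adjusted p = 4.3e-05, p = 0.27 with an estimated correlation) with 0 past either adjustment. There the ectodysplasin receptor gene Eda2r, from the p53 list (median 0.00, not called), rose adjusted over the list alone (0.85, SE 0.20). The receptor genes Grik2 (-0.27, SE 0.07) and Gabrd (-0.30, SE 0.09) fell in the same way, in a list with a median of 0.03 and no call. Lists of DNA repair (median 0.03) and polycomb genes (median -0.01) were not called.

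In BAC-CAG cortex at 6 months all 23 activity-regulated genes had positive signs (median 0.17, camera adjusted p = 0.00056, p = 0.70 with an estimated correlation), such as Btg2 (0.24, SE 0.13) and Junb (0.25, SE 0.15). Heat shock genes had a median of 0.04 there, and the small heat shock protein gene Hspb8 (0.48, SE 0.13, n = 8 each) rose adjusted over the list alone. In cortex at 12 months sterol synthesis genes had a median of -0.06, 23 of 24 negative (camera adjusted p = 1.0e-05, p = 0.76 with an estimated correlation), with Hmgcs1 at -0.14 (SE 0.04) and 0 past either adjustment. In BACHD striatum the reactive astrocyte genes C4b (0.27, SE 0.08) and Gfap (0.28, SE 0.08) rose adjusted over the list alone (median 0.06, camera adjusted p = 0.023, p = 0.61 with an estimated correlation). All 15 choroid plexus genes were negative in BACHD striatum (median -0.31, 0 past either adjustment, camera adjusted p = 0.00055, p = 0.61 with an estimated correlation). The complement gene C3, named after its values were seen, was at 0.628 ± 0.582 CPM in cortex of BAC-CAG mice at 12 months and 20.6 ± 37.0 CPM in WT mice (SD, n = 8 each), where 2 WT libraries held most of it (log2 change -5.00, edgeR adjusted p = 0.21).

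The test of a lower share of projection neurons was chosen after seeing the result, and those of cortical tissue, of Pkp2 against Msantd1 and of the splits were written before the data were examined. For the lower identity genes in BAC-CAG striatum at 12 months, a lower share of projection neurons with every other cell type higher alike is what the tables argue against. The microglial score differed by -0.140, and 5 of 5 other cell type scores were lower, 3 of them with an exact permutation p under 0.05. These 5 lists left out the cortical excitatory neurons, whose genes were higher, and the 2 libraries with high cortical scores were kept. The test thus speaks only to the form in which all other cell types rise alike. A lower share of projection neurons as such stays open. Cortical tissue in 2 BAC-CAG striatal libraries could lower the striatal genes. The difference without both was -0.226 (SE 0.084, exact permutation p = 0.023). By the rule written beforehand this argues against these 2 libraries as its only cause. With a margin of its SE, which was not part of that rule, the difference fell short of the limit. How much of the difference they add stays open. A lower expression of these genes within the neurons stays open as well, since the tables hold no counts of cells.

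Whether Pkp2 follows the Msantd1 level of the animal was tested within groups of BAC-CAG striatal libraries (r = -0.341, n = 22, permutation p = 0.12, adjusted over 3 relations p = 0.18, rho = -0.379 with permutation p = 0.082, r = -0.232 without the 2 farthest animals), which leaves it open.

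Splits of the libraries into mixed groups show which counts chance can give, counting the real one among them. Few splits reached the number of genes in BAC-CAG striatum at 12 months (1 of 100 had as many as 64, highest other 44). The same held at 6 months in striatum (2 of 100 had 2 or more, highest other 1221) and cortex (2 of 100 had 2 or more, highest other 32). These shares were not adjusted over the comparisons, so they make chance less likely there without excluding it. More splits reached the number of genes in striatum at 2 months (11 of 100 had 1 or more, highest other 62) and cortex at 2 months (7 of 100, highest 4). So it was in cortex at 12 months (13 of 100, highest 745) and BACHD cortex (6 of 34, real 1, highest 92), and chance cannot be excluded for these counts. In BACHD striatum 2 of 34 had 6 or more (highest other 56), so chance cannot be excluded. Single splits that call several times the real count, up to 1221 and 745 genes, point to a structure of the samples other than genotype, which was not tested further. For lists chance cannot be excluded in any comparison, with 38, 28 and 5 of 100 splits as high in striatum at 2, 6 and 12 months (real 15, 13 and 16, highest other 21, 17 and 17). In cortex these were 15, 64 and 52 of 100 (real 10, 6 and 8, highest other 13, 19 and 14), and in BACHD mice 28 of 34 in striatum (6, highest 17) and 20 of 34 in cortex (8, highest 15). The median of the other splits was 13, 10 and 10 lists in BAC-CAG striatum and 6, 6 and 8 in cortex. In BACHD mice it was 9 in striatum and 8 in cortex. Camera calls with the preset correlation were thus common in mixed groups too, so their small p values overstate the evidence.

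For interactions, 3 of 100 splits reached the 1 gene between striatum and cortex of BAC-CAG mice at 12 months (highest other 72). Animals moved with both tissues in these splits, and the share was not adjusted over the tests. That gene was lost with the animal as a block and without the low-count filter, so the call itself stays uncertain. Chance cannot be excluded for BACHD striatum against cortex (6 of 34, real 2, highest other 186) or between the lines in striatum (12 of 100, real 1, highest other 75). Where the real count was 0, all 100 of 100 splits were as high by construction, which tests nothing. The highest others were 7, 104 and 59 for the ages in striatum (2 against 6, 6 against 12 and 2 against 12 months), 95 for the ages in cortex, and 45 and 1 for the tissues at 2 and 6 months. They were 62 for the lines in cortex and 3 and 1 for the sexes at 6 and 12 months.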
